A study of Mus musculus with 27 samples.

How the data were processed

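The series measured gene expression in single T cells of female NOD/ShiLtJ mice, a strain that develops autoimmune diabetes. T cells that carried the beta chain of the T cell receptor and CD11a, an integrin chain raised on antigen-experienced cells, were sorted from pancreas, pancreatic lymph node and blood. Blood leukocytes came from a density gradient, and the pancreas was digested with collagenase and DNase before a Percoll step. The mice had received an isotype control antibody (IgG2a, clone 2A3; not diabetic, 16 weeks old), a blocking antibody against the inhibitory receptor PD-1 (clone 29F.1A12; diabetic, 16 weeks old), or no antibody and became diabetic spontaneously (18 weeks old). Antibody was given intraperitoneally as 0.2 mg on each of days -4 and -2. Each condition had 3 mice, whose cells were stained with hashtag antibodies and pooled, so that each tissue and condition made 1 library of 10x 5' version 2 chemistry and the 9 libraries hold 27 mouse samples.

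The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 6.1.0, per the file headers, on the mouse build mm10. Besides genes, the deposited counts cover the hashtag antibodies and a barcode named NRPv7. R 4.0.3 and Seurat 4.0.2 are named per the submitters' processing notes, with no parameters in the sources used here. The hashtag and NRPv7 counts were read from the 9 gene expression matrices, and separate files of the other 18 samples, of antigen receptor and feature-barcode libraries, were not analysed here.

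The filtered matrices held 74087 barcodes. Barcodes with at least 200 detected genes and under 10% mitochondrial UMIs were kept, which left 73337. Hashtag counts were assigned to mice per library with HTODemux in Seurat 5.3.0 on centred log-ratio values, with a positive quantile of 0.99. This gave 58995 singlets, 8685 doublets and 5657 barcodes without a hashtag, and the singlets alone were used. CD8-gated cells had at least 1 UMI of Cd8a or Cd8b1 and none of Cd4, and CD4-gated cells had at least 1 UMI of Cd4 and none of Cd8a or Cd8b1. Both gates also required a UMI of Cd3d, Cd3e, Cd3g, Trac, Trbc1 or Trbc2 and none of Cd79a, Ms4a1, Csf1r or C1qa. The gates held 16004 and 18902 cells, of which 2731 CD8-gated and 11262 CD4-gated cells passed on 1 UMI. The remaining 24089 singlets fell in neither gate, 22532 of them without a UMI of Cd4, Cd8a or Cd8b1.

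Cells are not replicates, so UMIs were summed per mouse, tissue and class, with at least 20 cells per sum. The sums were tested with edgeR 4.0.16 in R 4.3.3, with trimmed-mean normalisation, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjusted p below 0.05 within each comparison. Conditions were compared within a tissue over its 9 sums. Tissues were compared over all 27 sums of a class with condition as a covariate. The difference of the anti-PD-1 against spontaneous effect between tissues was an interaction contrast over the same 27 sums. Shifts of 24 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Shares of cells per mouse were compared with exact two-sided permutation tests, whose smallest possible p at 3 against 3 mice is 0.1. The mice were taken as independent, and the 3 mice of a condition shared 1 library, so that condition and library cannot be told apart in any comparison.

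These designs, the gates, the gene lists and the rule for naming genes were set before the data were examined. By that rule the text may name 13 fixed genes in every comparison. It may also name the genes with the largest fold among those with adjusted p below 0.05, an average log2 CPM (counts scaled to a common library total) of at least 4 and no overlap between the mice of the groups, 10 each way in the pancreas and between tissues and 5 each way elsewhere. Receptor and immunoglobulin segments, sex-linked genes and unnamed gene models were left out of that selection. Up to 4 members of each list with the lowest adjusted p complete it. With 3 against 3 mice, 10% of unchanged genes show no overlap by chance. Log2 fold changes are edgeR's fitted values with their standard errors, and CPM values were computed from the deposited counts per mouse sum.

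Cells were also clustered in scanpy 1.11.5 with leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 1), which gave 30 clusters, used for an alternative definition of the classes and to say where the gated cells of each library lay. Cluster sizes were not tested between groups. For UMI shares each cell was also thinned to 1000 UMIs, leaving out shallower cells. NRPv7-binding cells were those above the 99th percentile of the NRPv7 count in CD4-gated cells of the same library, and binding and other CD8-gated cells of the pancreas were compared with a term per mouse, where both sums held at least 20 cells. That comparison and the test of the condition effect between CD8-gated and CD4-gated cells were chosen after the data were seen. Intervals of shares of single libraries are exact binomial and cover counting error only.

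The alternatives were normalisation by relative log expression, no filter beyond 1 count, DESeq2 1.42.0, a hashtag rule of 80% of at least 10 hashtag counts, at least 500 genes, classes from clusters, at least 2 UMIs of a gate gene, a fit of only the conditions compared, and leaving out each mouse. Alternatives chosen after the data were seen were deep cells (at least 1500 UMIs passing both hashtag rules), leaving out cells with 1% or more acinar UMIs, leaving out the anti-PD-1 library labelled lymph node, and a stricter percentile for NRPv7. The labels do not say whether a hashtag marks the same mouse in each tissue, and the check of this is given with the alternatives.

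Each test was tested on simulated data with known folds. The spread of each gene was estimated from the real sums with only the changed group set apart, so other differences between sums entered it. For the interaction these included the tissues, and for the NRPv7 comparison the mice. The shares recovered therefore describe the simulated data and may differ from those of the real tests. At 1.5-, 2- and 4-fold the condition test recovered 19.4%, 65.7% and 95.4% of changed genes (9237 genes), the tissue test 53.7%, 83.6% and 93.9% (8913 genes), and the interaction 0%, 10.4% and 54.5% (9508 genes). The same folds were recovered at 34.8%, 80.3% and 98.3% in the NRPv7 comparison (7380 genes) and at 0%, 13.4% and 50% between the classes (9222 genes). False calls made up 3.3%, 6.1% and 0% of the calls of the condition test, the tissue test and the interaction. They made up 6.9% in the NRPv7 comparison and 6.7% between the classes.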

Results

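Gene expression was counted in single T cells sorted from the pancreas, pancreatic lymph node and blood of NOD mice. NOD mice develop autoimmune diabetes, in which T cells destroy the insulin-producing beta cells of the pancreatic islets. The 3 conditions were isotype-treated mice without diabetes, mice made diabetic by an antibody that blocks the inhibitory receptor PD-1, and mice with spontaneous diabetes, with 3 mice in each. Pancreas libraries held 7481 barcodes and 18516004 UMIs (isotype), 3943 and 13113985 (anti-PD-1), and 9502 and 23697723 (spontaneous). Libraries labelled lymph node held 5439 barcodes and 17594318 UMIs, 10038 and 13146847, and 8553 and 22255194 in the same order. Libraries labelled blood held 8486 and 22049913, 11156 and 34978081, and 9489 and 23260697. The anti-PD-1 library labelled lymph node was the shallowest, with a median of 836 UMIs per barcode against 1999 to 2774 in the other 8. In that library 42.19% of barcodes were assigned to 1 mouse, and 78.08% held under 1500 UMIs.

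The lymph node and blood libraries held transcripts at levels that differed from their labels, so they are called pLN-labelled and blood-labelled throughout. Platelet genes summed to 6.48, 32.48 and 9.53 CPM in the pLN-labelled libraries (isotype, anti-PD-1, spontaneous) and to 0.32, 0.23 and 0.34 CPM in the blood-labelled libraries. Erythroid genes were at 3.07 against 0.23 CPM in isotype and 7.99 against 0.31 CPM in anti-PD-1 libraries. In spontaneous libraries they were at 2.25 against 212.07 CPM. The pancreas libraries held 572.4, 529.7 and 689.7 CPM of these genes (isotype, anti-PD-1, spontaneous). The follicular helper, regulatory T cell and B cell lists were lower in the pLN-labelled library in all 3 conditions, and so were the lists of receptor stimulation, inhibitory receptors and glycolysis. Higher in all 3 were the cytotoxic, NK cell, macrophage, neutrophil and proliferation lists, the memory list and that of egress and lymphoid homing. Digestive enzyme genes of pancreatic acinar cells reached 404.9 CPM in the blood-labelled spontaneous library, 34.4 CPM in isotype and 13.7 CPM in anti-PD-1, against 2.02, 1.82 and 3.80 CPM in the pLN-labelled libraries. Every direction below that involves these 6 libraries rests on labels these values put in doubt.

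**Figure D1:**
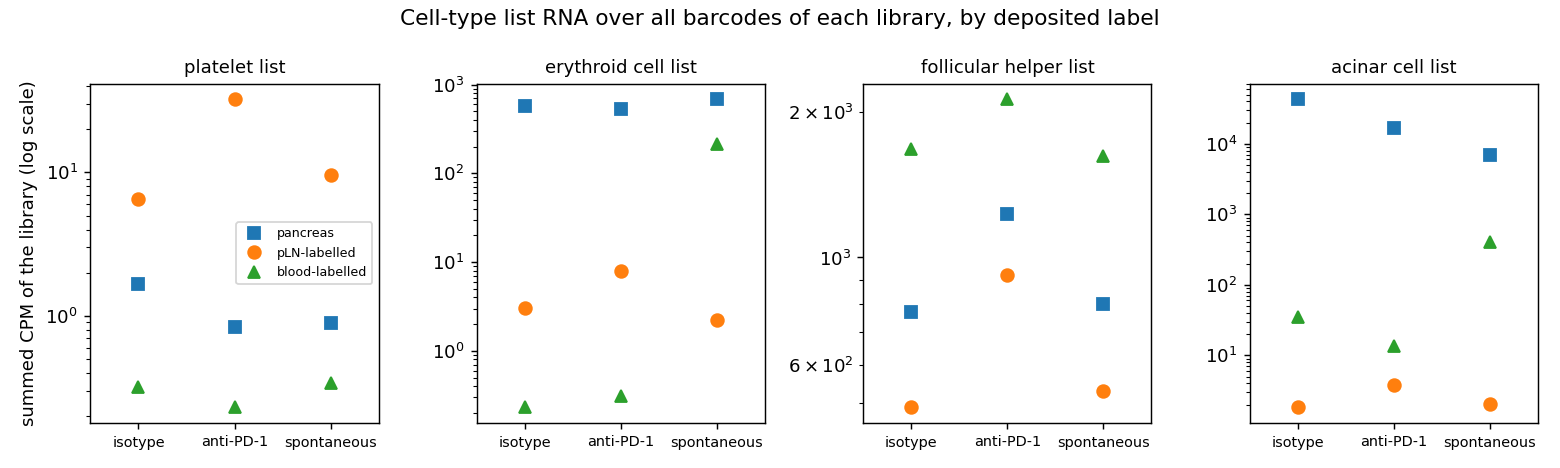
Summed CPM over all barcodes of a library (y axis, log scale) for 4 gene lists, by condition (x axis), with squares for pancreas, circles for pLN-labelled and triangles for blood-labelled libraries. Platelet genes sat at 6.48 CPM or more in the pLN-labelled libraries and at 0.34 CPM or less in the blood-labelled libraries.

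The first comparison asked how pancreas T cells of anti-PD-1-induced diabetes differed from those of spontaneous diabetes. In CD8-gated cells, several inhibitory receptor and exhaustion genes were higher after anti-PD-1, but their list did not pass with an estimated correlation. Pdcd1, which encodes PD-1 itself (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553 in mm10), rose by a log2 fold change of 1.10 ± 0.16 (SE, 3 against 3 mice, edgeR adjusted p = 0.000858). Havcr2, which encodes the inhibitory receptor TIM-3 (chromosome 11, 46454931 to 46481255), rose by 1.45 ± 0.26, and Tox, a transcription factor of exhausted cells (chromosome 4, 6686353 to 6991557), by 0.97 ± 0.17 (adjusted p = 0.003 for both). The proliferation marker Mki67 (chromosome 7, 135689784 to 135716450) rose by 1.68 ± 0.32, from 19.6 to 55.1 CPM (adjusted p = 0.0042). Slamf6, a receptor of progenitor-like exhausted cells (chromosome 1, 171917458 to 171948958), rose by 0.63 ± 0.17 (adjusted p = 0.027), and the cytokine gene Ifng (chromosome 10, 118441046 to 118445894) by 0.63 ± 0.18 (adjusted p = 0.033). Lag3, another inhibitory receptor, was at 0.69 ± 0.22 (adjusted p = 0.054), the granule protease gene Gzmb at 0.83 ± 0.34 (0.12), and Tcf7, a transcription factor of memory and progenitor cells, at 0.31 ± 0.17 (0.23). Cxcr6, Foxp3, Itgae and Cd69 did not pass either, at 0.23 ± 0.15, -0.52 ± 0.43, -0.12 ± 0.24 and 0.04 ± 0.21.

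In this comparison 684 genes rose and 533 fell of 9354 tested. Cluster 6 (Ccl4, Ccl3, Nr4a2) held 73.1% of these anti-PD-1 and 62.2% of these spontaneous cells, and cluster 25 (Mki67, Ube2c) 6.1% and 0.8%. Of 13 inhibitory receptor genes 8 rose, 9 adjusted over the list alone, with Ctla4 at 1.55 ± 0.19 beside Pdcd1 and Havcr2 (camera adjusted p = 1.3e-09, and adjusted p = 0.42 with an estimated correlation). Of 19 proliferation genes 9 rose, 16 adjusted over the list alone, among them the mitotic genes Ube2c at 2.40 ± 0.42 and Ccnb2 at 2.15 ± 0.49 (camera adjusted p = 1.8e-05, and adjusted p = 0.65 with an estimated correlation). Of 8 follicular helper genes 5 rose, 5 adjusted over the list alone, with Tox2 at 1.80 ± 0.27 and the costimulatory receptor Icos at 0.96 ± 0.14 (7.9e-05, and adjusted p = 0.42 with an estimated correlation). The cytotoxic list had 5 of 19 genes higher and 1 lower, with the same counts adjusted over the list alone, including the chemokine genes Ccl4 at 0.97 ± 0.15 and Ccl5 at 0.86 ± 0.14 (0.022, and adjusted p = 0.66 with an estimated correlation). Of 17 heat shock and immediate early genes 6 fell and 1 rose, with the same counts adjusted over the list alone, and Hspa1b was at -2.90 ± 0.63 (0.044, and adjusted p = 0.66 with an estimated correlation). The survival gene Bcl2 fell by 1.33 ± 0.09, the cytokine-induced inhibitor Cish by 1.36 ± 0.15, and S1pr5, a receptor for exit into the circulation, by 3.82 ± 0.81.

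Other genes with large rises were read 1 by 1. Mbd2, a reader of methylated DNA, rose by 2.31 ± 0.11, the phosphatase subunit gene Ppp2cb by 2.67 ± 0.16, Ybx3 by 1.98 ± 0.13 and the kinase gene Akt1 by 1.96 ± 0.15. Mbd2 also rose in CD4-gated cells, by 2.21 ± 0.13, and 167 genes were higher in both gates of this 1 library. The count of 1217 genes became 588 with DESeq2. It became 476 and 589 without the anti-PD-1 mice of Hashtag1 and Hashtag3, and 717 and 679 without the spontaneous mice of Hashtag2 and Hashtag4. Ifng and Slamf6 each lost their call in 4 of the 6 fits that left out 1 mouse.

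**Figure D2:**
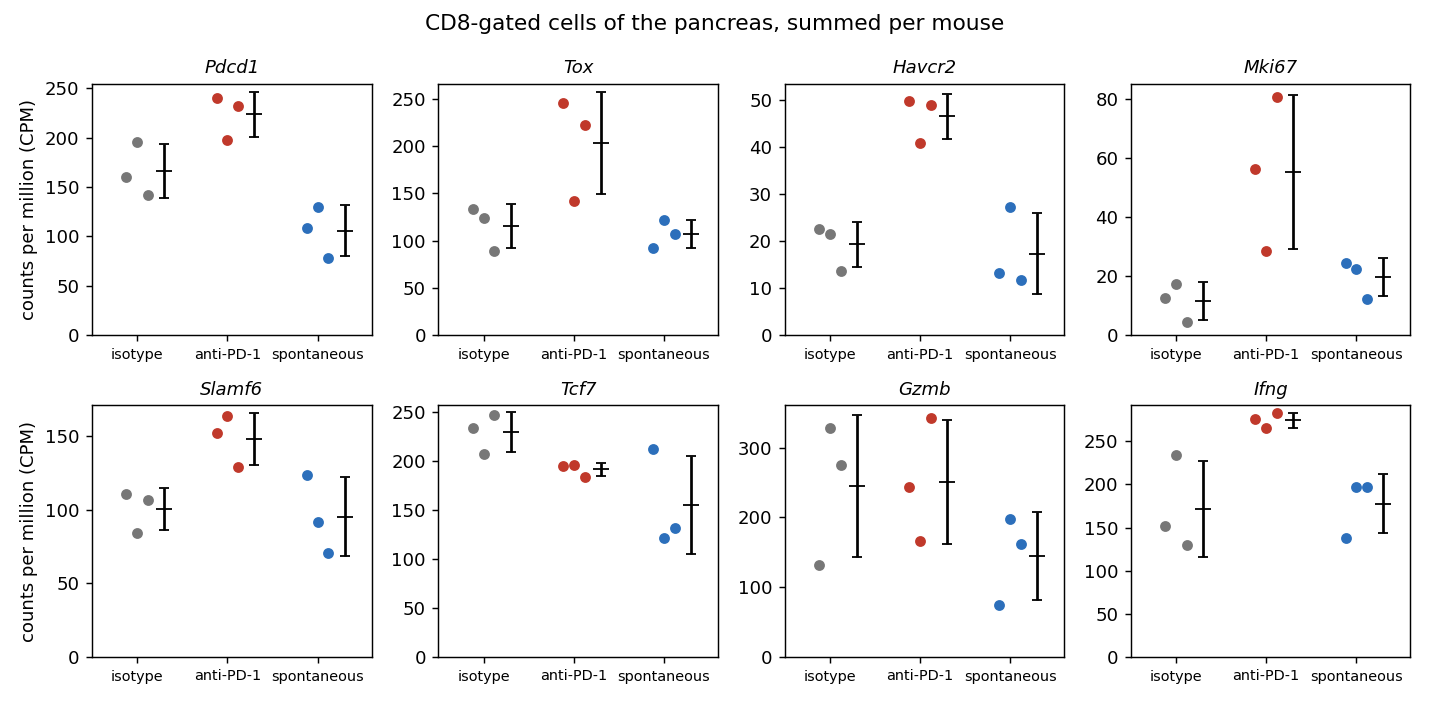
CPM per mouse (y axis) of 8 genes in CD8-gated pancreas cells by condition (x axis), with 1 point per mouse and black bars for the mean and SD of 3 mice. Mki67 averaged 55.1 CPM in anti-PD-1 and 19.6 CPM in spontaneous mice.

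Against isotype mice, which differed from anti-PD-1 mice in both antibody and diabetes, 693 genes rose and 614 fell in CD8-gated pancreas cells. The isotype cells were split otherwise between clusters, with 37.4% in cluster 6 and 0.8% in cluster 25, and with 24.7% in cluster 17, led by acinar genes, which held 2.2% of anti-PD-1 and 4.6% of spontaneous cells. Mki67 rose by 2.43 ± 0.37 (adjusted p = 0.00075), Havcr2 by 1.30 ± 0.27, Tox by 0.87 ± 0.18, the inhibitory receptor gene Tigit by 0.92 ± 0.15 and the chemokine gene Ccl3 by 2.22 ± 0.20. Ifng rose by 0.69 ± 0.18 and Cxcr6 by 0.52 ± 0.16, and these lost their call in 4 and 5 of 6 fits that left out 1 mouse. Pdcd1 was at 0.45 ± 0.16 (adjusted p = 0.073), Lag3 at 0.59 ± 0.23 (0.095) and Slamf6 at 0.53 ± 0.17 (0.057). Of 19 cytotoxic genes 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 3e-04), 8 of 13 inhibitory receptor genes rose (10 alone, 2e-06) and 10 of 19 proliferation genes rose (14 alone, 1.3e-06). All 3 of these lists had adjusted p = 0.42 with an estimated correlation. All 13 acinar genes fell, also adjusted over the list alone, Pnlip by 2.90 ± 0.17 and Cpa1 by 2.93 ± 0.20 (camera adjusted p = 1.9e-65, and adjusted p = 0.022 with an estimated correlation). Cells with at least 1% acinar UMIs made up 37.09% of the isotype, 6.23% of the anti-PD-1 and 5.14% of the spontaneous pancreas library. The count of 1307 genes became 735 with DESeq2. It became 636 and 792 without the anti-PD-1 mice of Hashtag1 and Hashtag3, and 744 without the isotype mouse of Hashtag4.

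Spontaneous diabetic mice were compared with isotype mice to see what diabetes without anti-PD-1, and 2 more weeks of age, went with. In CD8-gated pancreas cells 97 genes rose and 135 fell. Pdcd1 fell by 0.65 ± 0.16 (adjusted p = 0.049), a call lost in 4 of 6 fits that left out 1 mouse, and Izumo1r, which encodes folate receptor 4, by 0.64 ± 0.15. Tcf7 was at -0.58 ± 0.16 (adjusted p = 0.084). All 13 acinar genes fell, also adjusted over the list alone, with Pnlip at -2.62 ± 0.16 (camera adjusted p = 2.4e-102, and adjusted p = 0.0069 with an estimated correlation). The largest rise among the named genes was mt-Atp8, at 1.53 ± 0.10, which overlaps its neighbouring gene and is therefore uncertain. The count of 232 genes became 452 without a filter on low counts and 153 without the spontaneous mouse of Hashtag3.

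In CD4-gated pancreas cells of anti-PD-1 against spontaneous mice, 240 genes rose and 131 fell of 8528. Gzmb (ENSMUSG00000015437, chromosome 14, 56258836 to 56262334) rose most among the fixed genes, by 2.84 ± 0.25 (adjusted p = 2.7e-07). Mki67 rose by 1.64 ± 0.29 (adjusted p = 0.0018), Tcf7 by 0.67 ± 0.12 (0.0019) and Foxp3, the defining transcription factor of regulatory T cells (chromosome X, 7579676 to 7595243), by 0.69 ± 0.18 (0.033). Slamf6 rose by 0.54 ± 0.14 (adjusted p = 0.025) and Tox by 0.58 ± 0.16 (0.036), while Pdcd1 was at 0.47 ± 0.16 (0.098), Lag3 at -0.14, Havcr2 at -0.25 and Ifng at -0.07. Of 10 regulatory T cell genes 5 rose, 6 and 1 fallen adjusted over the list alone, with Ctla4 at 1.13 ± 0.10, Ikzf2 at 0.78 ± 0.13 and the cytokine gene Il10 at 1.71 ± 0.37 (camera adjusted p = 7.6e-07, and adjusted p = 0.19 with an estimated correlation). Cluster 10, with Foxp3 among its leading genes, held 20.1% of CD4-gated pancreas cells in anti-PD-1, 10.6% in spontaneous and 8.5% in isotype mice. Of 10 follicular helper genes 5 rose, 6 adjusted over the list alone, with Tox2 at 1.31 ± 0.23 (7.6e-07, and adjusted p = 0.19 with an estimated correlation). Of 14 proliferation genes 4 rose, 8 adjusted over the list alone (3e-05, and adjusted p = 0.21 with an estimated correlation). Hspa1b fell by 3.12 ± 0.59 and Penk, the gene of the opioid precursor proenkephalin, by 1.68 ± 0.36.

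The call of Foxp3 was lost in 5 of 6 fits that left out 1 mouse, and those of Slamf6 and Tox in 4 of 6 each. The count of 371 genes became 585 without a filter on low counts, 193 with DESeq2 and 878 with classes taken from clusters. It became 155 without the anti-PD-1 mouse of Hashtag1 and 231 without the spontaneous mouse of Hashtag2.

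Against isotype mice, CD4-gated pancreas cells of anti-PD-1 mice had 322 genes higher and 208 lower. Gzmb rose by 2.91 ± 0.26, Mki67 by 1.51 ± 0.30, Ctla4 by 1.34 ± 0.11 and Maf, a transcription factor of helper cells, by 1.05 ± 0.13, and Foxp3 was at 0.56 ± 0.18 (adjusted p = 0.077). Of 10 regulatory T cell genes 4 rose, 5 adjusted over the list alone (camera adjusted p = 2.8e-05, and adjusted p = 0.17 with an estimated correlation). Hspa1a fell by 4.48 ± 0.68, and all 13 acinar genes fell, also adjusted over the list alone, with Clps at -2.49 ± 0.15 (camera adjusted p = 1.5e-90, and adjusted p = 0.012 with an estimated correlation). In these cells 105 genes were higher and 107 lower in spontaneous than in isotype mice. Tcf7 fell by 0.56 ± 0.12 (adjusted p = 0.0082), a call lost in 1 of 6 fits that left out 1 mouse, Maf rose by 0.56 ± 0.13, and all 13 acinar genes fell (5.7e-99, and adjusted p = 0.0079 with an estimated correlation). The 530 genes against isotype became 262 with DESeq2, 1155 with classes from clusters, 325 without the isotype mouse of Hashtag4 and 248 without the anti-PD-1 mouse of Hashtag1. The 212 genes became 342 without a filter and 526 with classes from clusters.

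Shares of cells were compared per mouse for the same genes. Cells with an Mki67 UMI made up 9.82% ± 3.28 (SD, n = 3 mice) of CD8-gated pancreas cells after anti-PD-1, 2.33% ± 0.67 in spontaneous and 1.95% ± 1.07 in isotype mice. After thinning every cell to 1000 UMIs the shares were 3.35% ± 0.34, 1.14% ± 0.21 and 0.76% ± 0.55. The exact permutation p against either group was 0.1, the smallest that 3 against 3 mice allow, before and after thinning. Foxp3 was seen in 15.1% ± 3.49, 8.12% ± 1.09 and 9.04% ± 0.70 of CD4-gated pancreas cells (anti-PD-1, spontaneous, isotype), with a background of 1.26%, 1.51% and 1.19% in CD8-gated cells. Thinned, these were 8.94% ± 3.90, 4.97% ± 0.67 and 6.03% ± 0.51, with exact p of 0.3 against spontaneous and 0.4 against isotype mice. CD8-gated cells were 59.9% ± 7.88, 62.5% ± 8.37 and 59.0% ± 7.13 of the gated pancreas cells (exact p = 0.8 for anti-PD-1 against either). Leaving out 1 mouse at a time put these 2 differences between -5.831 and 2.237 and between -3.163 and 5.279 percentage points. Median depth was 3103, 2095 and 2139 UMIs in CD8-gated and 2663, 1990 and 1987.5 in CD4-gated cells, and thinning left out 4.04%, 4.88% and 10.4% of pancreas cells as too shallow.

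In the pLN-labelled libraries the same conditions were compared to ask whether the differences reach beyond the pancreas. In CD8-gated cells, anti-PD-1 against spontaneous mice had 116 genes higher and 42 lower of 9091. Genes of regulatory and follicular helper cells rose, with Izumo1r at 2.90 ± 0.22, Ikzf2 at 2.96 ± 0.39, Foxp3 at 2.78 ± 0.63 (adjusted p = 0.04) and Maf at 3.19 ± 0.54. Pdcd1 rose by 2.78 ± 0.60 (adjusted p = 0.036), Lag3 (ENSMUSG00000030124, chromosome 6, 124904359 to 124912434) by 2.35 ± 0.31 (0.0027), and the myeloid signalling gene Fcer1g by 3.42 ± 0.46. Cytotoxic genes fell, 7 of 19 and 16 adjusted over the list alone, with Prf1, the gene of perforin, at -1.65 ± 0.32 (camera adjusted p = 2.9e-21, and adjusted p = 0.06 with an estimated correlation). Of 9 regulatory T cell genes 5 rose, 6 adjusted over the list alone (7.3e-17, and adjusted p = 0.018 with an estimated correlation), and of 8 follicular helper genes 5 rose, 7 adjusted over the list alone (1.9e-18, and adjusted p = 0.0078 with an estimated correlation). Of 15 type I interferon genes 5 rose, 13 adjusted over the list alone, and Ifi27l2a was at 2.35 ± 0.36 (1.9e-18, and adjusted p = 0.043 with an estimated correlation). Of 6 macrophage genes 3 rose, 6 adjusted over the list alone (2e-13, and adjusted p = 0.035 with an estimated correlation). Against isotype mice 91 genes rose and 52 fell, with Tcf7 at 1.34 ± 0.25 (adjusted p = 0.026), Lag3 at 1.52 ± 0.30 and Gzmb at -2.19 ± 0.48. Cytotoxic genes fell there too, 10 of 19 and 17 adjusted over the list alone (2e-25, and adjusted p = 0.072 with an estimated correlation).

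By cluster, 74.2% of these CD8-gated cells in isotype and 65.4% in spontaneous mice lay in cluster 4 (Gzma, S1pr5, Cx3cr1), against 9.7% in anti-PD-1 mice. Of the anti-PD-1 cells 39.8% lay in cluster 11 (Gm2000, Ms4a6d, Ifi27l2a) and 17.6% in cluster 22 (Lyz2, Tyrobp, Fcer1g), which drew 90.4% and 96.0% of their cells from this library. The anti-PD-1 cells came from the shallow library, where CD8-gated cells had a median of 1233 UMIs against 1842 in spontaneous and 2041.5 in isotype mice. With deep cells only, the counts of 158 and 143 genes became 16 and 22, and with the 80% hashtag rule 37 and 39, and the calls of Foxp3 were lost under both. Fcer1g against isotype mice turned to -0.57 in deep cells. The count against spontaneous mice became 34, 71 and 19 without the anti-PD-1 mice of Hashtag1, Hashtag2 and Hashtag3, and 261, 35 and 47 without the spontaneous mice of Hashtag2, Hashtag3 and Hashtag4. The count against isotype mice became 8, 40 and 6 without the anti-PD-1 mice of Hashtag1, Hashtag2 and Hashtag3, and 612, 20 and 23 without the isotype mice of Hashtag2, Hashtag3 and Hashtag4. Without a filter on low counts the counts were 666 and 708, and with classes from clusters 1152 and 1294. Against spontaneous mice the count was also 97 with at least 500 genes per cell and 295 in a fit of the 2 conditions alone. In these fits Pdcd1 lost its call against spontaneous mice in 5 of 6 and Foxp3 in 4 of 6, and against isotype mice Tcf7, Lag3 and Gzmb lost theirs in 5 of 6 each. Spontaneous against isotype mice had 20 genes higher and 19 lower, led by near-copy genes such as Rps18 at -1.74 and H2-Q6 at -1.60, which are uncertain. That count of 39 became 163 without a filter and 24 without the spontaneous mouse of Hashtag3.

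In CD4-gated cells of the pLN-labelled libraries, interferon-induced genes rose after anti-PD-1. Against spontaneous mice 168 genes rose and 83 fell of 8301, and 11 of 16 type I interferon genes rose, 15 adjusted over the list alone. Isg15, an antiviral ubiquitin-like protein, was at 2.08 ± 0.24 and Ifit3 at 2.04 ± 0.44 (camera adjusted p = 3.4e-48, and adjusted p = 0.01 with an estimated correlation). Pdcd1 rose by 1.38 ± 0.24, Gzmb by 2.26 ± 0.50 and Lag3 by 1.24 ± 0.32, while the early activation gene Cd69 fell by 0.53 ± 0.12 and the interleukin-7 receptor gene Il7r by 0.81 ± 0.11. Macrophage genes moved in the same library, with 4 of 6 higher, 5 adjusted over the list alone, and Cybb at 2.03 ± 0.33 (5.2e-07, and adjusted p = 0.096 with an estimated correlation). Against isotype mice 211 genes rose and 127 fell, and 12 of 16 type I interferon genes rose, 14 adjusted over the list alone (7.8e-35, and adjusted p = 0.036 with an estimated correlation). Foxp3 rose by 0.85 ± 0.20, Lag3 by 2.28 ± 0.39 and Pdcd1 by 0.86 ± 0.23, and Fasl, the gene of a death ligand, fell by 1.79 ± 0.29. For spontaneous against isotype mice 45 genes were higher and 37 lower.

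Cluster 2 (Pgap1, Ccr7) held 68.0% of these CD4-gated cells in isotype, 61.3% in spontaneous and 32.4% in anti-PD-1 mice, where clusters 11 and 22 held 26.1% and 16.1%. Lag3 against spontaneous mice lost its call in 5 of 6 fits that left out 1 mouse, and Pdcd1 against isotype mice in 3 of 6. The count of 251 became 379 without a filter, 140 with DESeq2 and 146 without the anti-PD-1 mouse of Hashtag1. The count of 338 became 200 with DESeq2, 511 with classes from clusters, 206 without the isotype mouse of Hashtag2 and 203 without the anti-PD-1 mouse of Hashtag2. With classes from clusters Cybb against isotype mice turned to -0.39. The count of 82 became 151 without a filter, 52 with DESeq2, 483 with classes from clusters and 42 without the isotype mouse of Hashtag2. CD8-gated cells were 49.9% ± 1.47, 63.7% ± 7.37 and 62.7% ± 16.2 of gated cells (anti-PD-1, spontaneous, isotype; exact p = 0.1 and 0.4 for anti-PD-1 against these).

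In the blood-labelled libraries CD8-gated cells of anti-PD-1 against spontaneous mice had 91 genes higher and 59 lower of 8429. Gzmb rose by 1.55 ± 0.29 (adjusted p = 0.0074), Lag3 by 0.67 ± 0.15 (0.025), Pdcd1 by 0.62 ± 0.14 (0.026) and Tigit by 0.95 ± 0.18. Lgals3, a lectin gene of activated cells, rose by 2.01 ± 0.24, S100a4 by 1.48 ± 0.20 and the integrin gene Itga4 by 0.81 ± 0.08. Of 11 inhibitory receptor genes 3 rose, 5 adjusted over the list alone (camera adjusted p = 4.9e-05, and adjusted p = 0.094 with an estimated correlation). Of 14 proliferation genes 2 rose, 11 adjusted over the list alone (8.9e-12, and adjusted p = 0.084 with an estimated correlation). Of 15 type I interferon genes 4 rose, 13 adjusted over the list alone (5.2e-15, and adjusted p = 0.12 with an estimated correlation). The acinar genes Ctrb1 and Prss2 fell, at -7.51 ± 0.97 and -4.27 ± 0.64, beside the high acinar level of the spontaneous library. Against isotype mice 174 genes rose and 120 fell, with Lag3 at 1.11 ± 0.16, Pdcd1 at 0.89 ± 0.14 and Gzmb at 1.14 ± 0.27. Of 19 cytotoxic genes 8 rose there, 11 adjusted over the list alone (2.1e-12, and adjusted p = 0.059 with an estimated correlation).

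Spontaneous against isotype mice had 3 genes higher and 3 lower in these cells. Higher were the acinar genes Ctrb1 at 6.08 ± 0.90 and Prss2 at 4.39 ± 0.72, and Lars2 at 0.41 ± 0.07. Lower were Pcbp1 at -1.17 ± 0.10, Tle5 at -0.88 ± 0.08 and Arglu1 at -0.69 ± 0.12. Pcbp1, Tle5 and Arglu1 are also among the genes tested below for a property of the pancreas anti-PD-1 library. The count of 150 genes became 399 without a filter, 82 with DESeq2, 324 with classes from clusters, 254 without the anti-PD-1 mouse of Hashtag3, and 39 and 73 without the spontaneous mice of Hashtag2 and Hashtag3. The count of 294 became 578 without a filter, 130 with DESeq2, 166 without the anti-PD-1 mouse of Hashtag2, and 184, 114 and 115 without the isotype mice of Hashtag2, Hashtag3 and Hashtag4. The count of 6 became 99 without a filter, 12 with the 80% hashtag rule, 17 with classes from clusters and 25 in a fit of the 2 conditions alone. It became 2 without the isotype mouse of Hashtag3 or of Hashtag4, and 12, 3 and 29 without the spontaneous mice of Hashtag2, Hashtag3 and Hashtag4. Gzmb against isotype mice lost its call in 4 of 6 fits that left out 1 mouse, and Lag3 and Pdcd1 against spontaneous mice in 3 and 2 of 6.

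In CD4-gated cells of the blood-labelled libraries, several regulatory and cycling cell genes rose after anti-PD-1. Against spontaneous mice neither list passed with an estimated correlation (camera adjusted p = 0.072 for both). Against spontaneous mice 366 genes rose and 272 fell of 10066, with Mki67 at 1.96 ± 0.26 (adjusted p = 0.00039), Foxp3 at 0.51 ± 0.10 (0.0086), Pdcd1 at 0.61 ± 0.12, Tigit at 1.12 ± 0.13 and the epithelial-binding integrin gene Itgae at 1.04 ± 0.19. Of 11 regulatory T cell genes 7 rose, 9 adjusted over the list alone (camera adjusted p = 9.7e-12, and adjusted p = 0.072 with an estimated correlation). Of 19 proliferation genes 9 rose, 13 adjusted over the list alone, with the histone gene Hist1h1b at 3.21 ± 0.62 (3.7e-11, and adjusted p = 0.072 with an estimated correlation). Of 11 inhibitory receptor genes 4 rose, 9 adjusted over the list alone (7.4e-09, and adjusted p = 0.013 with an estimated correlation). Of 16 type I interferon genes 11 rose, 15 adjusted over the list alone, and Ifit3 was at 3.16 ± 0.86 (5.1e-14, and adjusted p = 0.2 with an estimated correlation). Of 5 acinar genes 4 fell, 5 adjusted over the list alone (2.9e-15, and adjusted p = 0.013 with an estimated correlation). Against isotype mice 395 genes rose and 332 fell, with Mki67 at 1.22 ± 0.23, Foxp3 at 0.49 ± 0.10 and Pdcd1 at 0.56 ± 0.11. Spontaneous against isotype mice had 13 genes higher and 40 lower, with Tcf7 at -0.47 ± 0.10 (adjusted p = 0.03), a call lost in 5 of 6 fits that left out 1 mouse.

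Foxp3 was seen in 24.2% ± 3.05, 15.9% ± 1.07 and 16.4% ± 0.45 of CD4-gated blood-labelled cells (anti-PD-1, spontaneous, isotype; 12.7%, 9.85% and 9.68% thinned), against 6.79%, 5.35% and 6.36% of CD8-gated cells. The exact p of anti-PD-1 against spontaneous mice was 0.1 before and after thinning, at median depths of 2839.5, 2195 and 2438 UMIs in CD4-gated and 3033.5, 2351 and 2871.5 in CD8-gated cells. With classes from clusters Foxp3 lost its calls in both anti-PD-1 comparisons. The count of 638 genes became 1048 without a filter, 334 with DESeq2 and 1014 with classes from clusters. It became 363 and 961 without the anti-PD-1 mice of Hashtag1 and Hashtag3, and 277, 245 and 417 without the spontaneous mice of Hashtag2, Hashtag3 and Hashtag4. The count of 727 became 1186 without a filter, 413 with DESeq2 and 1189 with classes from clusters. It became 427 and 1098 without the anti-PD-1 mice of Hashtag1 and Hashtag3, and 460, 356 and 421 without the isotype mice of Hashtag2, Hashtag3 and Hashtag4. The count of 53 became 155 without a filter and 106 with classes from clusters. It became 34, 32 and 25 without the isotype mice of Hashtag2, Hashtag3 and Hashtag4, and 34, 30 and 33 without the spontaneous mice in that order.

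Tissues were compared over all 9 mice per tissue, with condition as a covariate, to ask how T cells of the inflamed pancreas differ from those elsewhere. The cells compared lay in different clusters. The largest share of CD8-gated pancreas cells lay in cluster 6 (37.4% to 73.1%), that of blood-labelled cells in clusters 19 (Eomes, Gzmm; 24.0% to 34.7%) and 20 (Ccr9, Itgae; 31.5% to 46.1%), and that of pLN-labelled cells in cluster 4 or, after anti-PD-1, 11. The largest share of CD4-gated pancreas cells lay in cluster 5 (Fos, Cd40lg; 41.1% to 46.2%) and that of pLN-labelled cells in cluster 2 (32.4% to 68.0%), and blood-labelled cells were spread over more clusters, with at most 26.0% in any. CD8-gated pancreas cells against blood-labelled cells had 1600 genes higher and 1597 lower of 9247. Ifng rose by 3.77 ± 0.26, Havcr2 by 2.97 ± 0.27, Gzmb by 2.51 ± 0.39, the tissue-homing receptor gene Cxcr6 (chromosome 9, 123806477 to 123811754) by 1.95 ± 0.17 and Pdcd1 by 1.16 ± 0.18. Itgae (chromosome 11, 73090505 to 73147449) fell by 1.20 ± 0.17 and Foxp3 by 2.02 ± 0.32. Of 19 cytotoxic genes 16 rose, of 13 inhibitory receptor genes 11 rose, and of 14 memory genes 10 fell, each with the same count adjusted over the list alone. Of 17 heat shock and immediate early genes 12 rose, also adjusted over the list alone, with Fos at 5.33 ± 0.29, and the pancreas is the tissue for which the labels state enzymatic digestion. All 13 acinar genes rose beside them. Against pLN-labelled cells 1074 genes rose and 948 fell, with Pdcd1 at 3.66 ± 0.23, Lag3 at 2.77 ± 0.20, Tox at 2.31 ± 0.20 and S1pr5 at -4.60 ± 0.31. With classes from clusters Foxp3 and Mki67 against blood-labelled cells turned to 0.13 and -0.50, from -2.02 and 1.12.

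CD8-gated pLN-labelled against blood-labelled cells had 1669 genes higher and 1788 lower. Among single genes, S1pr5 rose by 5.27 ± 0.37, with Zeb2 at 4.34 ± 0.32, Klrg1 at 3.96 ± 0.33, Cx3cr1 at 3.79 ± 0.34 and the granzyme gene Gzma at 4.19 ± 0.53. Tnfrsf9 and Egr1, of the receptor stimulation list, fell by 4.27 ± 0.37 and 3.22 ± 0.22, and Pdcd1 was at -2.50 ± 0.26. Of 19 cytotoxic genes 17 rose, the same adjusted over the list alone, and of 15 receptor stimulation genes 11 fell, with 1 rise as well adjusted over the list alone. In CD4-gated cells 2016 genes rose and 1834 fell between these labels. Foxp3 fell by 1.36 ± 0.11, 11 of 12 regulatory T cell genes fell, 12 adjusted over the list alone, and Il21, a cytokine gene of follicular helper cells, fell by 5.62 ± 0.55, at 0.6 against 31.3 CPM. All 10 egress genes rose, also adjusted over the list alone, with the transcription factor gene Klf2 at 2.35 ± 0.08.

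CD4-gated pancreas cells had 1808 genes higher and 1613 lower than blood-labelled cells of 9121. Ifng rose by 3.54 ± 0.21, Havcr2 by 4.30 ± 0.33 and Cxcr6 by 2.23 ± 0.15, and all 10 type 1 helper genes rose, also adjusted over the list alone. Against pLN-labelled cells 986 genes rose and 1068 fell, with Lag3 at 4.07 ± 0.24, Pdcd1 at 2.33 ± 0.15, Il21 at 6.68 ± 0.50 and the lymph node homing receptor gene Ccr7 at -2.13 ± 0.09. Foxp3 was at -0.44 ± 0.09 against blood-labelled and 0.93 ± 0.12 against pLN-labelled cells. This last count of 2054 genes became 3247 with classes from clusters.

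Finally, the anti-PD-1 against spontaneous difference was compared between tissues. In CD8-gated cells the difference, taken with its sign, was higher in pancreas than in blood-labelled cells for 68 genes and lower for 5 of 9673. These were led by Mbd2 at 2.74 ± 0.17, Ybx3 at 2.77 ± 0.23 and Smad4, a mediator of TGF-beta signalling, at 2.52 ± 0.28. Of 13 acinar genes 9 were higher in this contrast, 13 adjusted over the list alone. Over all barcodes the acinar list was at 13.7 CPM in the anti-PD-1 and 404.9 CPM in the spontaneous blood-labelled library. In the pancreas libraries it was at 16753 and 7014 CPM. A higher value can thus come from a fall in blood-labelled cells as well as from a rise in pancreas. Against pLN-labelled cells 77 genes were higher and 50 lower, with Foxp3 at -3.25 ± 0.70 (adjusted p = 0.013), Fcer1g at -4.92 ± 0.70 and the chemokine gene Ccl4 at 2.29 ± 0.46. In CD4-gated cells 113 genes were higher and 11 lower against blood-labelled cells, with Mbd2 at 2.79 ± 0.17. Against pLN-labelled cells 70 were higher and 25 lower, with Slamf6 at 0.65 ± 0.17 (adjusted p = 0.045), a call lost in 10 of 12 fits that left out 1 mouse. Of 17 type I interferon genes in CD4-gated cells, 9 were lower against blood-labelled and 7 against pLN-labelled cells adjusted over the list alone, which did not pass over all genes tested.

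With deep cells only, Foxp3, Fcer1g and Ccl4 lost their calls in the CD8-gated contrast with pLN-labelled cells, and its count of 127 became 49. That count became 84 without the pancreas anti-PD-1 mouse of Hashtag1, 74 and 75 without the pLN-labelled anti-PD-1 mice of Hashtag1 and Hashtag3, and 318 and 79 without the pLN-labelled spontaneous mice of Hashtag2 and Hashtag4. It was 440 without a filter and 686 with classes from clusters, and it also rose with the hashtag as a replicate block, as given with the alternatives. The count of 73 against blood-labelled cells became 190 without a filter. In CD4-gated cells the count of 124 became 220 without a filter and 198 with classes from clusters. The count of 95 became 199 and 151 under the same settings, and 63 without the pancreas anti-PD-1 mouse of Hashtag1. It rose with the replicate block too.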

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

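Tests chosen only after the results were seen were the second test of the label pattern, the repeat of the library-wide test without 2 acinar genes, the setting of deep cells, the counts of other splits, the comparison of classes and the NRPv7 comparisons.

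The anti-PD-1 against spontaneous difference was itself compared between tissues. It differed for 73 genes in CD8-gated cells between pancreas and blood-labelled libraries, and for 127 between pancreas and pLN-labelled libraries. In CD4-gated cells it differed for 124 and 95 genes in the same order. Of 30 splits of the samples, which ignored the hashtag, 3, 2, 2 and 2 gave as many genes in these 4 contrasts, the real split included. The highest other split gave 137, 227, 317 and 186 genes, and each of these 4 kept the conditions apart in 1 tissue. Such a split keeps the real difference of that tissue, so the splits cannot decide on chance, which is not excluded for any of the 4 contrasts.

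The same difference was compared between CD8-gated and CD4-gated pancreas cells. It differed for 12 genes of 9369, with 8 higher and 4 lower in CD8-gated cells. Gzmb, the granule protease gene, was lower by this contrast at -2.00 ± 0.28, as was Cd40lg at -1.62, and Cd7 was higher at 0.94. DESeq2 called 0 genes. It had 218 of 9369 genes at an unadjusted p under 0.05, a share below 0.05, against 901 with edgeR. The 10 splits are too few for a share under 0.05, with 1 split at the real 12 and the highest other at 5. The count became 22 without the anti-PD-1 mouse of Hashtag2, and 4, 24 and 5 without the spontaneous mice of Hashtag2, Hashtag3 and Hashtag4.

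The NRPv7 barcode, outside the gene expression comparisons, was compared with its level in CD4-gated cells of the same library. It marked 18.2% of CD8-gated pancreas cells in isotype (387 of 2129, exact interval 16.6% to 19.9%), 17.4% in anti-PD-1 (267 of 1531, 15.6% to 19.4%) and 18.4% in spontaneous mice (571 of 3102, 17.1% to 19.8%). CD4-gated cells of these libraries were at 1.01%, 1.07% and 1.03%. In the pLN-labelled spontaneous library 1.67% of CD8-gated cells were marked (exact interval over cells 1.24% to 2.20%), against 1.01% of CD4-gated cells. Its mice were at 2.71%, 1.86% and 0.767%, and above a stricter percentile 3 of 2990 cells were left, so binding above background is not claimed there. Above that percentile 11.9%, 5.68% and 5.13% of CD8-gated pancreas cells were left (isotype, anti-PD-1, spontaneous).

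The pLN-labelled libraries held the higher platelet level in all 3 conditions, and the blood-labelled libraries the follicular helper, regulatory and B cell genes. The memory list and that of egress and lymphoid homing were higher in the pLN-labelled libraries in all 3, and were not part of the test of the labels. One explanation is that the labels of these libraries are exchanged, which needs both platelet and erythroid genes to be higher in the pLN-labelled library in all 3 conditions. They were in 2, since erythroid genes of the spontaneous pair went the other way, at 2.25 against 212.07 CPM. That blood-labelled library also held 404.9 CPM of acinar genes, against 2.02 CPM in its pLN-labelled pair. Acinar genes were at 34.4 against 1.82 CPM in isotype and 13.7 against 3.80 CPM in anti-PD-1 libraries (blood-labelled against pLN-labelled). The pancreas libraries held 572.4, 529.7 and 689.7 CPM of erythroid genes (isotype, anti-PD-1, spontaneous). Erythroid RNA thus need not mark blood, and the spontaneous pair cannot decide on the labels. A second explanation, blood cells carried into the lymph node libraries, would leave circulating effector cells in the blood-labelled libraries too, and S1pr5, Cx3cr1 and Klrg1 summed to at most 0.175 of the pLN-labelled level there, but these genes were picked after they were seen to differ, so the value excludes nothing. The NK cell list was at 1.77, 2.52 and 2.19 CPM there, against 84.17, 50.51 and 86.9 CPM in the pLN-labelled libraries (isotype, anti-PD-1, spontaneous). The platelet and cytotoxic lists were also lower there in all 3 conditions, the erythroid list in 2 and the B cell list in 0. These lists were set beforehand. With the labels as given, the values argue against carried blood cells as the source of the NK cell and cytotoxic differences. Blood leukocytes came from a density gradient, which may have changed their platelet and erythroid content, so the platelet and erythroid lists cannot decide. The exchange of labels stays open, as does a difference in how the samples were prepared, which was not tested.

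In the pancreas, 167 genes were higher in anti-PD-1 than spontaneous mice in both gates. The test used 47 genes outside the acinar list, among them Mbd2, Ppp2cb, Ybx3 and Akt1. For all 47 the difference, taken with its sign, was higher in pancreas than in blood-labelled cells in both gates. Their sum had a log2 ratio of 0.95 in CD8-gated and 0.955 in CD4-gated cells. Against isotype mice it was -0.005 and 0.075, and 2 acinar genes were in the sum. A property of a library may be the cause, in which case barcodes without T cell genes should show it too, and they did at 2.24, but 2 acinar genes (Sycn and 2210010C04Rik) gave 2502 of the 2942 UMIs, or 85.0%. Without these, in a repeat that followed the first result, the ratio was 0.16 (exact interval -0.05 to 0.37, 440 against 340 UMIs) against 1.05 in CD8-gated cells, and -0.253 against 0.324 with isotype mice. Of the 440 UMIs, Mbd2, Ppp2cb, Ybx3 and Akt1 held 13, 2, 9 and 5, against 63 of Tle5 and 42 of Pcbp1. The ratio thus says little about Mbd2, Ppp2cb, Ybx3 and Akt1. The 440 and 340 UMIs came from 14 and 24 barcodes. The interval covers the counting error of UMIs only, not the spread between barcodes or mice. The library and the condition cannot be told apart for the 47 genes, because each condition of a tissue is 1 library.

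CD8-gated cells of the pLN-labelled anti-PD-1 library carried regulatory, follicular and myeloid transcripts. Free RNA in shallow barcodes may be the source, and the median log2 fold change of the 105 higher genes tested was 1.04 in all cells and 0.75 in deep cells, a ratio of 0.72. Of these, 10 were still called in deep cells. The lower genes had a ratio of 0.917 with 5 of 42 still called, and the higher genes of CD4-gated cells 0.962 with 105 of 162 still called. Free RNA and a change in the cells cannot be told apart here, since the deep cells are few and all from the same library.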

How the results depend on the processing

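The settings chosen only after the data were seen were the tests with deep cells, without cells rich in acinar UMIs, without the pLN-labelled anti-PD-1 library, those of NRPv7 binding and of the classes, and the block for the contrasts between tissues. Relative log expression normalisation moved none of the 30 gene counts by over 1.5 times, and 541 of 541 named values kept their direction and side of the threshold. Leaving out acinar-rich cells moved none of the 16 counts it was run on, and 14 of 385 named values lost their call. All 6 tissue counts kept within 1.5 times under every setting run except 1 below, also in the 108 fits without 1 mouse and without the pLN-labelled anti-PD-1 library. Of the named values that had passed, 68 lost their call with DESeq2, 64 with deep cells, 39 with the 80% hashtag rule and 36 with classes from clusters. For every value below the cause was not tested.

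Values are given in the order anti-PD-1 against spontaneous, anti-PD-1 against isotype, spontaneous against isotype, where all 3 moved. Without a filter on low counts, CD8-gated cells gave 452 genes in pancreas for spontaneous against isotype, 666, 708 and 163 in pLN-labelled, and 399, 578 and 99 in blood-labelled cells, with 190 and 440 in the tissue contrasts with blood-labelled and pLN-labelled cells. CD4-gated cells gave 585 and 342 in pancreas and 379 and 151 in pLN-labelled cells (first and last comparison), 1048, 1186 and 155 in blood-labelled cells, and 220 and 199 in the tissue contrasts. NRPv7 binding gave 507 and the class contrast 115. DESeq2 gave 588 and 735 in CD8-gated pancreas, 82 and 130 in CD8-gated blood-labelled, 193 and 262 in CD4-gated pancreas, 140, 200 and 52 in CD4-gated pLN-labelled, and 334 and 413 in CD4-gated blood-labelled cells. It gave 208 for NRPv7 binding and 0 for the class contrast, where edgeR called 12. In that contrast 218 of 9369 genes had an unadjusted p under 0.05 with DESeq2, a share below 0.05.

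Classes from clusters gave 1152 and 1294 in CD8-gated pLN-labelled cells, 324 and 17 in CD8-gated blood-labelled cells (first and last comparison) and 686 in the CD8-gated contrast with pLN-labelled cells. CD4-gated cells gave 878, 1155 and 526 in pancreas, 511 and 483 in pLN-labelled (last 2 comparisons) and 1014, 1189 and 106 in blood-labelled cells, 3247 for pancreas against pLN-labelled cells, and 198 and 151 in the tissue contrasts. Under this setting Cd83 in CD8-gated blood-labelled cells turned to 0.037 (anti-PD-1 against spontaneous). Foxp3 and Mki67 of CD8-gated pancreas against blood-labelled cells turned to 0.125 and -0.497. Cybb, Fcer1g and Tyrobp of CD4-gated pLN-labelled cells turned to -0.386, -0.501 and -0.94 (anti-PD-1 against isotype). In CD8-gated cells the 80% hashtag rule gave 37 and 39 in pLN-labelled and 12 in blood-labelled cells (spontaneous against isotype). At least 500 genes per cell gave 97 in pLN-labelled cells (anti-PD-1 against spontaneous). Deep cells gave 16 and 22 in pLN-labelled cells and 49 in the contrast with them, and Fcer1g there turned to -0.566 (anti-PD-1 against isotype). A fit of only the 2 conditions gave 295 in pLN-labelled (anti-PD-1 against spontaneous) and 25 in blood-labelled cells (spontaneous against isotype). A percentile stricter than the 99th gave 99 genes for NRPv7 binding.

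With an estimated correlation the lists past the threshold in CD8-gated cells went from 6 to 0 and from 6 to 1 in pancreas, from 12 to 6, 12 to 1 and 5 to 0 in pLN-labelled, and from 8 to 0, 8 to 1 and 6 to 1 in blood-labelled cells. In CD4-gated cells they went from 7 to 0 and 10 to 1 in pancreas, 9 to 5, 11 to 4 and 3 to 0 in pLN-labelled, and 10 to 2 and 10 to 1 in blood-labelled cells.

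Some differences of shares, in percentage points, changed sign. Thinned to 1000 UMIs, the CD8 share of anti-PD-1 was 0.117 above spontaneous mice in pancreas and 0.098 above isotype mice in blood-labelled cells. Foxp3 of CD8-gated cells was at -0.41 (anti-PD-1) and -0.228 (spontaneous) against isotype mice in pancreas, and at -0.228 (anti-PD-1) in blood-labelled cells. Spontaneous against isotype mice gave 0.373 for Mki67 of CD4-gated pancreas cells, 0.036 and 0.167 for Foxp3 of CD4-gated pLN-labelled and blood-labelled cells, and 0.004 for Mki67 of CD8-gated blood-labelled cells. Mki67 of CD8-gated pLN-labelled cells was at 0.497 and 0.151 (anti-PD-1 against spontaneous and isotype), and at 0.019 against spontaneous mice with 500 genes or more. The gate of 2 UMIs gave -3.095 for the CD8 share of pancreas (anti-PD-1 against isotype). Cells of 1500 UMIs that passed both hashtag rules gave -0.182 for Foxp3 of CD8-gated pancreas cells (anti-PD-1 against isotype), 0.811 for Mki67 of CD4-gated pancreas cells and -1.924 for the CD8 share of pLN-labelled cells (both spontaneous against isotype).

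Without 1 mouse at a time, CD8-gated gene counts ranged from 476 to 1380, 636 to 1504 and 153 to 182 in pancreas, 19 to 261, 6 to 612 and 24 to 58 in pLN-labelled, and 39 to 254, 114 to 311 and 2 to 29 in blood-labelled cells, and from 74 to 318 in the contrast with pLN-labelled cells. CD4-gated counts ranged from 155 to 334 and 248 to 423 in pancreas, 146 to 226, 203 to 281 and 42 to 100 in pLN-labelled, 245 to 961, 356 to 1098 and 25 to 34 in blood-labelled cells, and 63 to 86 in the contrast with pLN-labelled cells. NRPv7 binding ranged from 214 to 331 genes and the class contrast from 4 to 24. The CD8 share of pancreas ranged from -5.831 to 2.237, -3.163 to 5.279 and -1.315 to 6.557, of pLN-labelled cells from -6.605 to 9.487 (spontaneous against isotype) and of blood-labelled cells from -2.972 to 0.236 (anti-PD-1 against isotype). Foxp3 of CD8-gated cells ranged from -0.228 to 0.267 in pancreas and -0.128 to 1.062 in blood-labelled cells (anti-PD-1 against isotype), and from -0.123 to 0.422 in pLN-labelled cells (spontaneous against isotype). Spontaneous against isotype mice ranged from -0.217 to 0.829 and -0.493 to 0.228 for Mki67 of CD8-gated and CD4-gated pancreas cells, -0.531 to 0.19 for Foxp3 of CD4-gated pLN-labelled cells and -0.489 to 0.127 for Mki67 of CD8-gated blood-labelled cells. Mki67 of CD8-gated pLN-labelled cells ranged from -0.742 to 0.326 (anti-PD-1 against spontaneous). The NRPv7-binding share of pancreas ranged from -8.254 to 1.623, -7.978 to 1.899 and -2.995 to 2.091. Above the stricter percentile it turned to -6.865 for spontaneous against isotype mice in pancreas. In pLN-labelled cells it turned to 0.244 and -0.302 (first and last comparison), and in blood-labelled cells to 0.056 and 0.035 (first 2 comparisons).

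The tissues came from the same mice, but the labels do not say whether a hashtag marks 1 mouse across tissues, so all 27 sums of a class were treated as independent. Sums with the same hashtag and condition had deviations from their group means correlated at a median of 0.026 to 0.087, and at most 3 of 9 pairs were above 0.1 in any class and condition, so by the rule set before the files were read the hashtag was not taken to pair samples. The data hint that it may. Over receptor segments the median in CD8-gated cells was 0.075, 0.226 and 0.276 (isotype, anti-PD-1, spontaneous), with 4, 8 and 7 of 9 pairs above 0.1, against -0.0525, -0.123 and -0.132 for other hashtags. In each case a sum was set against 3 hashtags of another tissue, 1 of them its own. Sums correlated best with their own hashtag in 12, 16 and 16 of 18 cases over segments, and in 10, 11 and 16 over all genes. In CD4-gated cells this held in 10, 10 and 8 of 18 over segments and in 17, 16 and 16 over all genes. With the hashtag as a replicate block, the tissue comparisons called 1561 genes higher and 1554 lower, 1030 and 892, and 1628 and 1757 in CD8-gated cells, in the order pancreas against blood-labelled, pancreas against pLN-labelled and pLN-labelled against blood-labelled. In CD4-gated cells they called 1794 and 1624, 986 and 1063, and 1975 and 1811. The contrasts of the anti-PD-1 against spontaneous difference called 104 and 215 genes in CD8-gated and 166 and 174 in CD4-gated cells under the block (pancreas against blood-labelled, then pLN-labelled cells). None of the 252 named values lost its call under the block.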

Other observations

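The NRPv7 comparisons, the islet counts and the counts of other splits were tests chosen only after the results were seen.

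CD8-gated pancreas cells that bound NRPv7 were compared with the other CD8-gated cells of the same 8 mice, in which both sums held enough cells. NRPv7 is the name of a peptide that islet-reactive CD8 T cells of NOD mice recognise, but the sources used here do not describe the barcode. In binding cells 137 genes were higher and 187 lower of 7504. The total was 99 above a stricter percentile, 208 with DESeq2 and 507 without a filter on low counts. Receptor segments separated the cells most, with Trbv13-3 (ENSMUSG00000076470) at 3.37 ± 0.23 and Trav16n at 2.51 ± 0.26, and 4 of 28 segments were higher and 13 lower. Inhibitory receptor genes were higher, 10 of 12, with Pdcd1 at 1.04 and Tox at 1.08, as were 10 of 18 cytotoxic genes, with Nkg7 at 0.57 ± 0.06 and Ccl5 at 0.52, while 2 were lower. Memory genes were lower, 10 of 12, with Ccr7 at -2.36 ± 0.18 and Tcf7 at -0.77. Of 30 splits that exchanged the cell groups within mice, 1 gave as many as the real 324 genes, itself, and the highest other gave 16. That share is under 0.05 and is the smallest that 30 splits can give. Without the isotype mouse of Hashtag3 the count was 214.

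Per mouse, NRPv7-binding cells made up 18.0% ± 5.14 of CD8-gated pancreas cells in isotype, 14.4% ± 10.1 in anti-PD-1 and 18.3% ± 5.68 in spontaneous mice. Exact permutation p was 0.7 for anti-PD-1 against either group and 1.0 for spontaneous against isotype mice. Above a stricter percentile the shares were 12.2% ± 4.08, 4.56% ± 5.61 and 5.31% ± 2.15 in the same order. This percentile was fixed per library by the few highest of 1490, 931 and 1846 CD4-gated cells. Its error is shared by the 3 mice of a library and does not enter the p over mice. Exact permutation p was then 0.9 for anti-PD-1 against spontaneous, 0.3 for anti-PD-1 against isotype and 0.1, the smallest possible, for spontaneous against isotype mice, so the order of the groups rests on the percentile. The anti-PD-1 mouse of Hashtag2 stood lowest, with 7 of 209 cells (3.35%), and without it the anti-PD-1 mean was 1.62 percentage points above spontaneous mice in place of -3.89. Means in the pLN-labelled libraries were 1.39%, 1.17% and 1.78%, and in the blood-labelled libraries 1.31%, 0.872% and 1.07% (isotype, anti-PD-1, spontaneous).

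Insulin transcripts were counted in the pancreas libraries over the assigned cells of each mouse. Isotype mice had 24, 24 and 21 insulin UMIs, spontaneous mice 6, 20 and 5, and anti-PD-1 mice 0, 0 and 0 among 4216349, 1545891 and 5047286 UMIs, where a count of 0 allows up to 3. Islet genes summed to 6.19 ± 0.46 CPM in isotype, 2.66 ± 1.29 in spontaneous and 0.50 ± 0.70 in anti-PD-1 mice (SD, n = 3), and acinar genes to 20183 ± 2050, 5142 ± 1170 and 6234 ± 1907 CPM in the same order. The 3 mice of a condition were pooled in 1 library, so these SDs do not show the spread between separately processed mice. Per 10000 acinar UMIs the islet UMIs were 3.10 ± 0.51, 5.43 ± 2.93 and 0.74 ± 0.90, in these cells. Over all barcodes of a library they were 7.61 (609 islet UMIs), 3.37 (56) and 0.137 (3), so the order of isotype and spontaneous mice rests on the barcodes counted.

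Other splits of the samples were counted for each comparison. Between conditions the 10 splits of 6 mice are too few for a share under 0.05. In CD8-gated pancreas cells the real counts were 1217, 1307 and 232 (anti-PD-1 against spontaneous, anti-PD-1 against isotype, spontaneous against isotype) and the highest other splits 0, 0 and 2. These were 158, 143 and 39 with 0, 0 and 203 in pLN-labelled, and 150, 294 and 6 with 11, 1 and 1 in blood-labelled cells. In CD4-gated cells they were 371, 530 and 212 with 1, 0 and 0 in pancreas, 251, 338 and 82 with 2, 1 and 11 in pLN-labelled, and 638, 727 and 53 with 0, 0 and 3 in blood-labelled cells. The split with 203 genes calls several times the real 39 and points to a structure of those 6 mice other than condition. There 2 splits reached the real count, and in the other 17 comparisons 1 did, the real one. Between tissues 1 of 30 splits, the real one, reached the real count in all 6 comparisons, a share under 0.05. These splits took the sums as independent and ignored the hashtag. The 3 sums of a tissue and condition share 1 library, so the splits do not exclude a difference between libraries. The real counts were 3197, 2022 and 3457 in CD8-gated cells (pancreas against blood-labelled, pancreas against pLN-labelled, pLN-labelled against blood-labelled), with highest others of 0, 0 and 1. In CD4-gated cells they were 3421, 2054 and 3850, with 2, 1 and 816.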
